A study of Mus musculus with 21 samples.

How the data were processed

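Gene expression was measured by RNA sequencing in 21 libraries of 2 mouse cell lines. 1C11NE cells are 1C11 neuroectodermal stem cells that had been differentiated for 12 days toward a noradrenergic neuronal fate, and BV2 is an immortalised microglial line. Acrylamide, a reactive vinyl monomer that is toxic to nerve cells, was given at 1 mM for 24 h, and phosphate-buffered saline (PBS) was the vehicle. The 7 groups of 3 libraries were taken from the sample titles. They are PBS and ACR (1C11NE cells with vehicle or acrylamide), PBS-CM (1C11NE cells in medium conditioned by vehicle-treated BV2 cells), PBS-CM+ACR (that medium with acrylamide added), ACR-CM (medium conditioned by acrylamide-treated BV2 cells), BV2_PBS and BV2_ACR. The labels do not state whether acrylamide was removed from the ACR-CM medium, and they name different base media for the 2 cell lines, so PBS-CM and PBS may also differ in base medium. Nothing states that replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

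The values were the raw read counts per gene symbol that the authors deposited, whole numbers for 24263 symbols with no normalisation. Per the labels' protocols, poly(A) RNA was captured on oligo(dT) beads, the resulting whole-transcriptome libraries were fragmented by enzyme, and the products were sequenced on an Ion GeneStudio S5 instrument. Per the submitters' processing notes, Bowtie2 2.2.5 was among the tools used. The genome build, the annotation and the counting program are not given in the sources used here. Reads that fit several near-identical genes can be split or lost at that step. Values of Gstp1 and Gstp2, the ferritin light chain gene Ftl1, the histone genes and the ribosomal protein genes are therefore uncertain. Strand use in counting is not given either, so reads of overlapping genes cannot be told apart. Total counts per library ran from 2762287 to 7391991. Ribosomal RNA took 3.55 to 5.56% of the counts of a library. No 2 libraries of a group held the same values, and a chi-square statistic between replicates ran from 2.65 to 66.1 times its degrees of freedom, so no library was counted as a repeat of another.

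Everything that follows was computed from these counts. Libraries were scaled by the trimmed mean of M-values (TMM) and genes with too few counts were removed with edgeR's filterByExpr. Differences were tested with edgeR's quasi-likelihood test with a robust prior (edgeR 4.0.16, R 4.3.3) and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. The 15 libraries of 1C11NE shared a fit of 12550 genes, in which the biological coefficient of variation was 0.211. The 6 libraries of BV2 were fitted alone with 10890 genes and a coefficient of 0.136. All 21 libraries entered a joint fit of 13569 genes with a coefficient of 0.197, which served only to compare the acrylamide effect between the lines. Levels are CPM (counts scaled to a common library total after TMM), given as mean ± SD of 3 libraries, and log2 fold changes are given ± SE.

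The comparisons were ACR with PBS, PBS-CM with PBS, PBS-CM+ACR with PBS-CM, ACR-CM with PBS-CM, ACR-CM with PBS-CM+ACR and BV2_ACR with BV2_PBS. The model also gave 2 interaction terms, the acrylamide effect with conditioned medium minus that without it, and the acrylamide effect in BV2 minus that in 1C11NE. The named genes were fixed by rule. They are the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 20 CPM and no overlap between the compared groups, which chance gives for 10% of genes with 3 libraries against 3. For the interactions the rule took 6 in each direction with no condition on overlap. Predicted genes without an established name were passed over, and members of the fixed lists were added. Genes named outside this rule are said to be so, and a few genes that the rule picks are not reported here.

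The 22 gene lists covered targets of NRF2 with glutathione and NADPH enzymes, ATF4 targets, endoplasmic reticulum chaperones, heat shock response, proteasome subunits, cholesterol synthesis, cell cycle, p53 targets, noradrenergic identity, neuronal cytoskeleton and synapse, microglia markers, astrocyte and oligodendrocyte markers, embryonal carcinoma stem cell markers, NF-kB targets with cytokines and chemokines, alternative macrophage activation, interferon-stimulated genes, MHC class I presentation, immediate early genes, extracellular matrix, glycolysis and hypoxia, mitochondrially encoded genes and lysosome. Lists with at least 3 tested members were compared with all other genes by limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry, which tests whether a list's genes move one way or in either direction, were run beside it. Shared control libraries make comparisons correlate without any effect, so unchanged groups against the same controls were simulated in 20 draws.

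The groups, tests, lists, naming rule and a set of other settings were fixed before the data were examined. These settings were DESeq2's size factors in edgeR, no filter, a filter at 20 CPM, DESeq2 1.42.0, limma-voom, a fold threshold of 1.5, the replicate number as a block, a fit of the 6 compared libraries alone and each library left out in turn. Chosen after the data had been seen were a correction for GC content and transcript length, that correction together with the block, the omission of 2 libraries that stood far from their groups, and the pairing of ACR against PBS with ACR-CM against PBS-CM. GC content and length came from the longest GENCODE vM21 transcript of each symbol, with a match for 94.2% of the tested genes in 1C11NE and 94.7% in BV2. A setting meant for normalised values was not run, because the values are counts.

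The tests were checked on simulated counts with 200 changed genes. At a 2-fold change the share of changed genes called was 52.2% for ACR against PBS, 46.3% for PBS-CM against PBS, 40.3% for PBS-CM+ACR against PBS-CM, 44.8% for ACR-CM against PBS-CM, 37.3% for ACR-CM against PBS-CM+ACR and 68.7% for BV2. It was 4.48% for the conditioned medium interaction and 7.46% for the interaction between lines, and at a 4-fold change these rose to 63.6% and 50.0%. Of the genes called, 2.04 to 5.77% were unchanged in the simulation. Simulated genes varied independently, whereas in the 1C11NE libraries the first axis of the deviations within groups held 44.3% of their variance. These shares may therefore not carry over to the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.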

Results

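Transcript levels were measured in 2 mouse cell lines after 24 h with 1 mM acrylamide, with medium conditioned by microglia, or with both. The 15 libraries of 1C11NE cells, labelled as a noradrenergic neuronal model, fell into 5 groups of 3. The 6 libraries of BV2 microglial cells fell into 2 groups of 3. Library totals ran from 2762287 counts in PBS-CM+ACR replicate 1 to 7391991 in PBS replicate 2, so low transcripts were measured least precisely in PBS-CM+ACR. Across the 15 libraries of 1C11NE, the first principal component held 43.1% of the variance. PBS-CM replicate 1 and PBS-CM+ACR replicate 3 lay on the side of the libraries without conditioned medium, at -27.2 and -17.4, while the other 7 conditioned-medium libraries lay between 14.0 and 41.1.

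The comparison of ACR with PBS shows the direct response of 1C11NE cells to acrylamide. Transcripts for antioxidant and detoxifying enzymes rose. Prdx6, a peroxiredoxin that reduces phospholipid peroxides, rose 7.32-fold, from 89.3 ± 8.38 to 653 ± 50.8 CPM (log2 2.87 ± 0.21, n = 3 per group, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.8e-06). Nqo1, a quinone reductase, rose from 35.3 ± 6.36 to 134 ± 13.3 CPM, and Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, from 29.0 ± 3.19 to 107 ± 2.87 CPM. Ccnd1, which encodes cyclin D1 and drives entry into the cell cycle, fell 5.85-fold, from 57.0 ± 2.5 to 9.65 ± 2.30 CPM (edgeR adjusted p = 4.7e-06). In all, 58 genes were higher and 90 lower, and 1500 of 12550 had an unadjusted p under 0.05.

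Of the 26 genes in the list of NRF2 targets, glutathione and NADPH enzymes, 15 rose and 0 fell, and 25 rose when adjusted over the list alone. NRF2 is the transcription factor that switches on defences against electrophiles. The median log2 change was 1.23 and camera gave an adjusted p of 4.9e-45, or 0.00028 with an estimated correlation. Log2 increases were 2.21 ± 0.29 for the glutathione transferase Gsta4, 2.13 ± 0.20 for Blvrb, a biliverdin reductase, and 1.63 ± 0.18 for Srxn1, which restores oxidised peroxiredoxins. The glutathione transferases Gstp1 and Gstm1 rose by 2.00 ± 0.24 and 1.54 ± 0.20, and Gstp1 shares reads with its near copy Gstp2. Enzymes of the pentose phosphate pathway, which makes NADPH, rose as well, with 1.51 ± 0.19 for Pgd and 1.50 ± 0.21 for Taldo1. The ferritin subunits Fth1 and Ftl1, which store iron, rose by 1.21 ± 0.20 and 1.42 ± 0.22. Prdx6 is not in the list, and neither are Aldh3a1, an aldehyde dehydrogenase, and Esd, an esterase that acts on S-formylglutathione, which rose by 2.32 ± 0.33 and 1.58 ± 0.24.

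**Figure D1:**
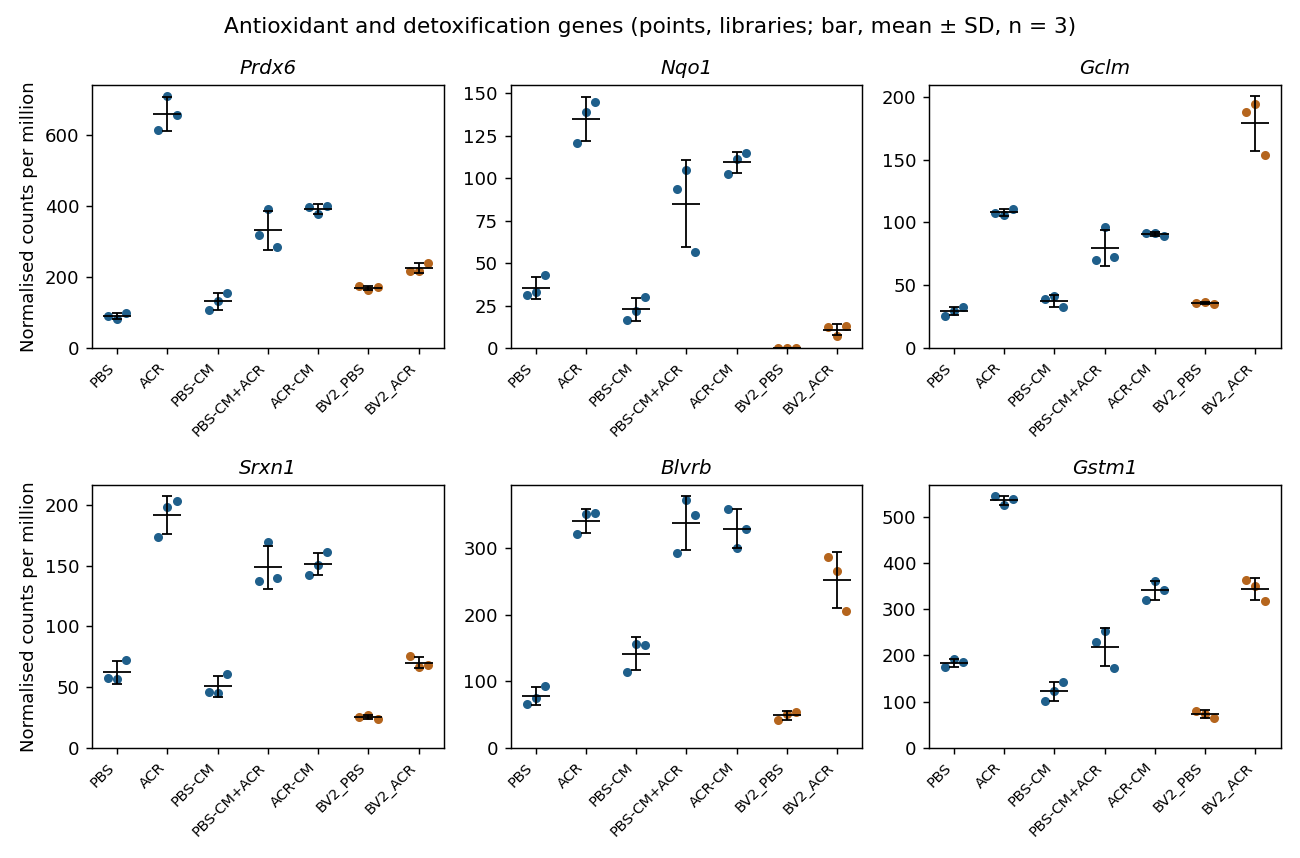
CPM (y axis, TMM-scaled counts) of Prdx6, Nqo1, Gclm, Srxn1, Blvrb and Gstm1 in each library of the 7 groups (points), with mean and SD of 3 libraries per group (horizontal lines and error bars). Prdx6 averaged 89.3 CPM in PBS and 653 in ACR, against 133 in PBS-CM and 391 in ACR-CM.

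Cholesterol synthesis was a second list whose median moved up, with 3 of 22 members called, 9 when adjusted over the list alone, and a median of 0.49 (camera adjusted p = 2.0e-08, and 0.0055 with an estimated correlation). The summed level of its members did not rise, at 2368 ± 360 CPM in PBS and 2327 ± 194 in ACR. Mvd, Cyp51 and Acat2, enzymes of the pathway, rose by 1.11 ± 0.20, 0.94 ± 0.17 and 0.86 ± 0.16. Of 12 genes in the list of NF-kB targets, cytokines and chemokines, 0 passed over all genes (edgeR) and 6 were higher when adjusted over the list alone (camera adjusted p = 0.0017, and 0.024 with an estimated correlation). MHC class I presentation had 1 of 14 members higher, the immunoproteasome subunit Psmb10 at 0.97 ± 0.17, and 2 over the list alone, with camera adjusted p = 0.0071 and 0.041 with an estimated correlation. Heat shock response (1 of 16 higher, Hspb1 at 0.71 ± 0.16) and proteasome subunits (0 of 31 by edgeR over all genes and over the list alone, median 0.37) passed camera at adjusted p = 9.3e-05 and 1.1e-07. With an estimated correlation these became adjusted p = 0.053 and 0.35.

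Extracellular matrix genes fell as a group. Of 18 members, 3 were called lower and 6 when adjusted over the list alone, with a median of -0.82 (camera adjusted p = 7.3e-10, and 0.0055 with an estimated correlation). The collagen genes Col3a1, Col1a1 and Col5a2 fell by 2.38 ± 0.39, 1.29 ± 0.27 and 1.18 ± 0.18 on the log2 scale. Outside the list, Col6a2 fell by 1.86 ± 0.27, the proteoglycan gene Vcan by 1.84 ± 0.18, the metalloprotease gene Adamts1 by 1.65 ± 0.33 and the stromal surface gene Cd248 by 1.71 ± 0.34. Other decreases were -1.97 ± 0.25 for Tenm4, a teneurin, -1.70 ± 0.40 for the semaphorin receptor Nrp2, -1.60 ± 0.35 for Gfra1, a GDNF receptor, and -1.44 ± 0.20 for the growth factor Ptn. Calls of Cd248 and Nrp2 ended without any 1 of the 6 libraries (edgeR adjusted p from 0.052 to 0.11 and from 0.078 to 0.21), of Gfra1 without any but PBS replicate 3 (0.069 to 0.17), and of Adamts1 without replicate 1 or 2 of PBS or of ACR (0.066 to 0.12). Aqp1, a water channel, and the nuclear RNA Neat1 changed by -1.97 ± 0.24 and -1.65 ± 0.18. Slc1a3, a glutamate transporter, changed by -1.80 ± 0.19 and was the 1 of 6 astrocyte and oligodendrocyte markers called, or 2 over the list alone (camera adjusted p = 0.0017, and 0.074 with an estimated correlation).

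Noradrenergic identity genes gave 0 calls among 6 tested by edgeR over all genes and 1 higher when adjusted over the list alone (camera adjusted p = 0.49). The list members Th and Dbh were not in the table and could not be tested. Among 12 neuronal cytoskeleton and synapse genes, Dpysl3 fell by 1.33 ± 0.26, and 4 were lower when adjusted over the list alone (camera adjusted p = 0.15). Immediate early genes (Jun at -1.13 ± 0.22 and Klf4 at -0.94 ± 0.14, camera adjusted p = 0.063), interferon-stimulated genes (0.063), ATF4 targets (0.22), microglia markers (0.21), cell cycle (0.32), lysosome (0.20), glycolysis and hypoxia (0.17, with Pdk1 at -1.15 ± 0.23), mitochondrially encoded genes (0.49), p53 targets (0.86), alternative macrophage activation (0.92) and endoplasmic reticulum chaperones (0.97) did not pass camera. Of the embryonal carcinoma stem cell markers 2 of 14 could be tested, too few for a list test. The number of called genes was 71, 72, 75 or 78 without PBS replicate 1, PBS replicate 2, ACR replicate 1 or ACR replicate 2. Leaving out PBS-CM replicate 1 and PBS-CM+ACR replicate 3, which enter through the shared spread only, raised it to 554.

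The comparison of PBS-CM with PBS sets medium from vehicle-treated microglia against plain medium. A possible difference in base medium enters it too and cannot be told apart from the conditioning. The Id genes, inhibitors of basic helix-loop-helix transcription factors and targets of BMP signalling, rose together. Id3 went from 38.3 ± 2.12 to 336 ± 55.5 CPM (log2 3.13 ± 0.20, n = 3 per group, edgeR adjusted p = 1.6e-07), Id1 from 54.5 ± 3.34 to 300 ± 65.7 CPM and Id2 from 19.3 ± 1.01 to 95.4 ± 13.8 CPM. Timp1, an inhibitor of matrix metalloproteases, rose from 123 ± 10.9 to 657 ± 170 CPM. Peg10, an imprinted gene derived from a retrotransposon, fell 46.7-fold, from 104 ± 4.04 to 2.2 ± 0.79 CPM (edgeR adjusted p = 1.7e-09). In all, 313 genes were higher and 258 lower, with 3219 of 12550 at an unadjusted p under 0.05.

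Further increases were 2.27 ± 0.21 for the lubricin gene Prg4, 2.13 ± 0.26 for Urah, 1.89 ± 0.26 for Ramp3, a receptor partner for adrenomedullin, 1.61 ± 0.20 for the ribonucleotide reductase subunit Rrm2, 1.58 ± 0.25 for Adssl1 and 1.38 ± 0.26 for Fgl2. Decreases were -3.02 ± 0.36 for Aldh3a1, -2.95 ± 0.47 for the inhibin subunit Inhbb, -2.29 ± 0.37 for Elfn2, -2.18 ± 0.19 for the chemokine Cxcl12, -1.98 ± 0.20 for Fmo1, a monooxygenase, -1.87 ± 0.26 for Hdac9, -1.84 ± 0.38 for Apcdd1, an inhibitor of Wnt signalling, -1.75 ± 0.35 for Fam43a and -1.73 ± 0.32 for Lrig1. Calls ended for Apcdd1 and Fam43a without PBS replicate 1 or 2 or PBS-CM replicate 2 or 3 (edgeR adjusted p from 0.072 to 0.10 and from 0.054 to 0.086), for Lrig1 without PBS replicate 1 or PBS-CM replicate 2 (0.065 and 0.067) and for Fgl2 without PBS replicate 1 (0.071).

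**Figure D2:**
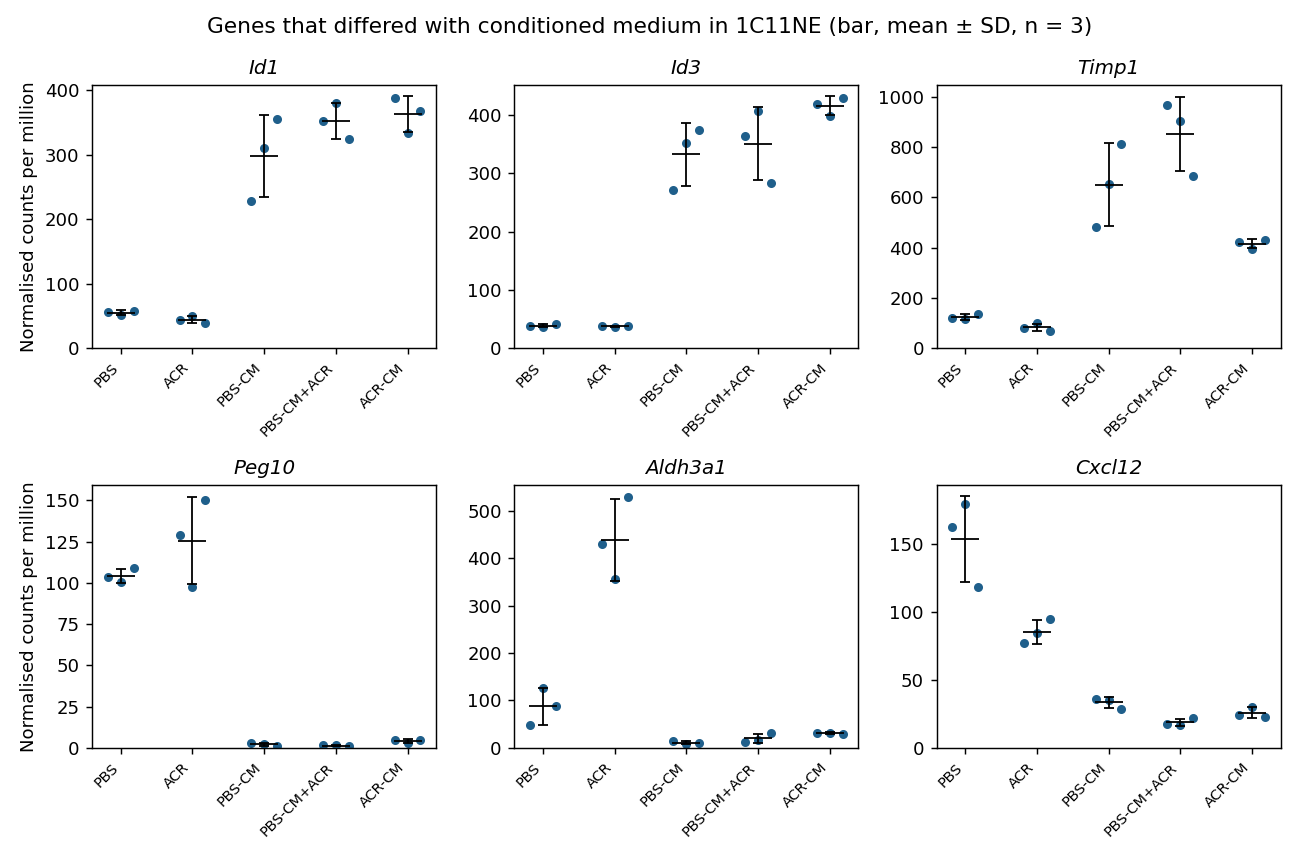
CPM (y axis, TMM-scaled counts) of Id1, Id3, Timp1, Peg10, Aldh3a1 and Cxcl12 in each library of the 5 1C11NE groups (points), with mean and SD of 3 libraries per group (horizontal lines and error bars). Peg10 averaged 104 CPM in PBS and 2.2 in PBS-CM, and Id3 38.3 and 336 CPM.

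Cholesterol synthesis fell, with 7 of 22 members lower and 1 higher, or 10 and 1 when adjusted over the list alone (median -0.40, camera adjusted p = 1.7e-06, and 0.031 with an estimated correlation). Msmo1, an enzyme of the pathway, changed by -1.35 ± 0.20, the sterol sensor Insig1 by -0.99 ± 0.15 and the regulator Srebf2 by -1.17 ± 0.30, while Pmvk rose by 0.90 ± 0.25. Interferon-stimulated genes had 4 of 20 members higher and 0 lower, 12 and 0 when adjusted over the list alone, with a median of 0.65 (camera adjusted p = 9.4e-06, and 0.072 with an estimated correlation). Their examples were Oas1a at 1.79 ± 0.44, Rtp4 at 1.76 ± 0.37, Bst2 at 1.51 ± 0.30 (not called without PBS replicate 1 or 2 or PBS-CM replicate 2 or 3, edgeR adjusted p 0.064 to 0.072) and Isg15 at 1.20 ± 0.22, and outside the list Ifitm3 rose by 1.43 ± 0.24. Proteasome subunits had 1 of 31 members higher and 9 over the list alone (median 0.44, camera adjusted p = 1.7e-06, and 0.54 with an estimated correlation). Immediate early genes had 3 of 19 lower (Egr1 at -1.58 ± 0.27, Atf3 at -1.34 ± 0.23 and Klf2 at -1.22 ± 0.31) and 1 higher (Junb at 1.15 ± 0.21), or 9 and 2 when adjusted over the list alone (camera adjusted p = 0.016, and 0.43 with an estimated correlation).

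Mitochondrially encoded genes had 0 of 13 called by edgeR over all genes and over the list alone, with a median of 0.40 (camera adjusted p = 0.034, and 0.84 with an estimated correlation). After a correction for GC content and length their direction reversed, at camera adjusted p = 0.00053. Microglia markers had 1 of 6 higher (camera adjusted p = 0.034, 0.17 with an estimated correlation, 0.18 with that correction, and 0.27 without PBS-CM replicate 1 and PBS-CM+ACR replicate 3). That gene was Ctss, a cysteine protease abundant in microglia, at 2.27 CPM in PBS-CM and 0 in every PBS library. Summed over all 21 microglia markers in the table, levels in 1C11NE ran from 65.6 ± 4.36 CPM in PBS to 97.54 ± 6.59 CPM in ACR-CM, against 7919 ± 489 CPM in BV2_PBS. Extracellular matrix genes had 3 higher of 18 (Timp1, Bgn at 1.39 ± 0.20 and Sparc at 0.84 ± 0.20) and, over the list alone, 3 higher and 3 lower (camera adjusted p = 0.92). The NRF2 list had 1 higher and 1 lower of 26, and 2 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.84). No other list passed camera.

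Ribosomal protein genes took 6.21 to 7.91% of the counts in PBS, 6.93% in PBS-CM replicate 1, and 11.8% and 13.4% in PBS-CM replicates 2 and 3. PBS-CM+ACR replicate 3 and ACR-CM replicate 2 held 7.63% and 7.99%, so the share was not raised in every library with conditioned medium. An effect of the medium on it cannot be told from differences between libraries of the same group. With the replicates left out in turn the number of called genes was 108, 142 and 291 without PBS replicates 1, 2 and 3, and 3233, 106 and 127 without PBS-CM replicates 1, 2 and 3. It was 4479 with both PBS-CM replicate 1 and PBS-CM+ACR replicate 3 left out, and 569 of the 571 genes were among them.

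Acrylamide in the presence of medium from vehicle-treated microglia (PBS-CM+ACR against PBS-CM) raised the same class of enzymes. Nqo1 rose from 22.9 ± 7.08 to 86.7 ± 25.8 CPM (log2 1.92 ± 0.25, n = 3 per group, edgeR adjusted p = 0.0022), Srxn1 from 51.0 ± 9.14 to 151 ± 15.6 CPM and Prdx6 from 133 ± 25.1 to 337 ± 52.98 CPM. Rgs2, a brake on G-protein signalling, fell from 164 ± 39.7 to 59.4 ± 11.9 CPM and Neat1 from 545 ± 23.1 to 205 ± 14.0 CPM. In all, 22 genes were higher and 25 lower, with 1087 at an unadjusted p under 0.05.

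Of the 26 genes in the NRF2 list, 11 rose and 0 fell, and 22 rose when adjusted over the list alone (median 0.96, camera adjusted p = 9.4e-43, and 0.00036 with an estimated correlation). Besides Nqo1 and Srxn1, Blvrb rose by 1.27 ± 0.20, Gclm by 1.10 ± 0.16, Pgd by 1.21 ± 0.19, Taldo1 by 1.14 ± 0.20, Ftl1 by 1.20 ± 0.22 and Gstp1 by 1.17 ± 0.24, and outside the list Esd by 1.45 ± 0.24. Cholesterol synthesis had 2 of 22 higher, among them Idi1 at 1.19 ± 0.20, and 3 over the list alone (camera adjusted p = 6.9e-08, and 0.0076 with an estimated correlation). The summed level of that list hardly differed, at 1260 ± 266 CPM in PBS-CM and 1275 ± 198 in PBS-CM+ACR. Calls ended for Pgd and Esd without PBS-CM replicate 2 (edgeR adjusted p = 0.052), for Esd also without PBS-CM+ACR replicate 2 (0.057), for Ftl1, Taldo1, Idi1 and Gstp1 without PBS-CM replicate 2 or PBS-CM+ACR replicate 1 or 2 (0.063 to 0.17), and for Gstp1 also without PBS-CM replicate 1 (0.068). Proteasome subunits had 0 of 31 called by edgeR over all genes and over the list alone (median 0.29, camera adjusted p = 1.2e-05, and 0.65 with an estimated correlation). Immediate early genes had 1 of 19 lower, Klf4 at -0.68 ± 0.14, and 5 lower and 1 higher over the list alone (camera adjusted p = 0.00062, and 0.34 with an estimated correlation). Extracellular matrix genes had 0 of 18 called by edgeR over all genes and over the list alone, with a median of -0.11 (camera adjusted p = 0.57), and no other list passed.

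Decreases in this comparison were -1.81 ± 0.37 for Cd248, -1.28 ± 0.21 for Ptn, -1.27 ± 0.25 for Tenm4, -1.16 ± 0.20 for the renin gene Ren1, -1.14 ± 0.23 for Aqp1, -1.09 ± 0.22 for Rin1, -1.09 ± 0.20 for Slc1a3, -1.04 ± 0.17 for Etnk2, and -1.45 ± 0.30 and -1.37 ± 0.28 for the histone genes Hist1h2ap and Hist1h2ag, which have near copies. Each of these calls ended without PBS-CM replicate 2 (edgeR adjusted p 0.052 to 0.22), all but those of Ptn and Etnk2 also without PBS-CM+ACR replicate 1 or 2 (0.11 to 0.26), those of Cd248, Tenm4, Aqp1 and Rin1 without PBS-CM replicate 1 (0.068 to 0.12), and those of the histone genes without replicate 3 of PBS-CM or PBS-CM+ACR (0.096 to 0.16). Without PBS-CM replicate 2, PBS-CM+ACR replicate 1, PBS-CM+ACR replicate 2 or PBS-CM+ACR replicate 3, 11, 17, 16 or 73 genes were called where all libraries gave 47. With only the 6 compared libraries in the edgeR fit 0 genes were called, with 536 at an unadjusted p under 0.05, while DESeq2 called 124 and limma-voom 48 in their own fits of all 1C11NE libraries.

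Medium from acrylamide-treated microglia (ACR-CM against PBS-CM) also raised these enzymes. Nqo1 rose 4.77-fold, from 22.9 ± 7.08 to 109 ± 6.78 CPM (log2 2.25 ± 0.25, n = 3 per group, edgeR adjusted p = 0.00051), Pgd from 132 ± 4.57 to 424 ± 50.6 CPM, and Prdx6 from 133 ± 25.1 to 391 ± 14.4 CPM. Thy1, a neuronal and stromal surface protein, fell from 33.4 ± 5.98 to 10.2 ± 0.40 CPM, and Prg4 from 36.8 ± 3.95 to 13.3 ± 0.43 CPM. In all, 56 genes were higher and 60 lower, with 1614 at an unadjusted p under 0.05.

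Of the 26 genes in the NRF2 list, 14 rose and 0 fell, and 23 rose when adjusted over the list alone (median 1.10, camera adjusted p = 5.1e-39, and 0.00037 with an estimated correlation). Of its members Gsta4, Srxn1 and Gstm1 increased by 1.65 ± 0.29, 1.57 ± 0.18 and 1.47 ± 0.20, with Gsta4 not called without ACR-CM replicate 1 (edgeR adjusted p = 0.051). Outside it, the glutathione synthetase gene Gss and the carbonyl reductase gene Cbr3 increased by 1.36 ± 0.18 and 1.37 ± 0.18. Cholesterol synthesis had 7 of 22 higher, and 14 when adjusted over the list alone (median 0.63, camera adjusted p = 1.8e-16, and 0.00037 with an estimated correlation). Msmo1 rose by 1.58 ± 0.20, Idi1 by 1.24 ± 0.20, Fdps by 1.10 ± 0.21 and Acat2 by 1.06 ± 0.16, and outside the list Lipn, a lipase, by 1.59 ± 0.22. Proteasome subunits (0 of 31 by edgeR, median 0.38), heat shock response (0 of 16, 2 higher over the list alone) and cell cycle (0 of 26) passed camera at adjusted p = 4.8e-10, 0.00075 and 0.012. With an estimated correlation these were adjusted p = 0.38, 0.11 and 0.38.

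The extracellular matrix list had 0 of 18 members called by edgeR and 2 lower over the list alone, with a median of -0.57 (camera adjusted p = 0.00031, and 0.11 with an estimated correlation). Glycolysis and hypoxia genes had 1 higher, Aldoa at 0.94 ± 0.17, and 1 lower, Pdk1 at -1.01 ± 0.23 (camera adjusted p = 0.0052, and 0.15 with an estimated correlation). Among astrocyte and oligodendrocyte markers Slc1a3 changed by -0.87 ± 0.19 (camera adjusted p = 0.0021, and 0.11 with an estimated correlation). Other decreases were -1.81 ± 0.40 for Dennd4b, -1.56 ± 0.35 for Gfra1, -1.44 ± 0.23 for the aldose reductase relative Akr1b7, -1.41 ± 0.32 for the natriuretic peptide receptor Npr2, -1.41 ± 0.32 for Oaf, -1.24 ± 0.24 for Tenm4 and -1.21 ± 0.23 for Aqp1. Of these, all but Akr1b7 lost the call without PBS-CM replicate 1 or any ACR-CM library (edgeR adjusted p 0.054 to 0.27), Dennd4b, Gfra1, Npr2 and Oaf without PBS-CM replicate 2 (0.061 to 0.085), and Oaf without PBS-CM replicate 3 (0.052). The call count was 74 and 59 without PBS-CM replicates 1 and 2 and 35, 44 and 47 without ACR-CM replicates 1, 2 and 3, and 15 with only the 6 compared libraries in the fit.

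ACR-CM and PBS-CM+ACR were compared directly, since both groups met BV2-conditioned medium. Pmepa1, a negative regulator of TGF-beta signalling, fell from 18.3 ± 4.62 to 3.09 ± 1.36 CPM (log2 -2.55 ± 0.29, n = 3 per group, edgeR adjusted p = 0.0014), and is named here after its values were seen. With edgeR 0 genes were higher and 2 lower, with 688 at an unadjusted p under 0.05, DESeq2 called 15 and limma-voom 2. Cholesterol synthesis was higher in ACR-CM, with 0 of 22 called over all genes and 6 over the list alone (median 0.30, camera adjusted p = 7.5e-06, and 0.019 with an estimated correlation). ATF4 targets, genes of amino acid supply and stress, had a median of 0.23 with 0 of 25 called and 1 over the list alone (camera adjusted p = 0.00070, and 0.019 with an estimated correlation). Their summed level was 6380 ± 200 CPM in ACR-CM and 5783 ± 411 in PBS-CM+ACR. In PBS-CM it was 6415 ± 49.9, so ACR-CM did not stand above its control.

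Another 10 lists passed camera in this comparison and were lost with an estimated correlation. Higher in ACR-CM were cell cycle (camera adjusted p = 1.0e-05, and 0.18 with an estimated correlation), heat shock response (0.012, and 0.18), proteasome subunits (0.014, and 0.70), glycolysis and hypoxia (0.025, and 0.18), endoplasmic reticulum chaperones (0.029, and 0.18), immediate early genes (0.038, and 0.39) and the NRF2 list (0.039, and 0.39). Lower were extracellular matrix (0.0010, and 0.15), alternative macrophage activation (0.029, and 0.35) and neuronal genes (0.038, and 0.35). Without PBS-CM replicate 1 and PBS-CM+ACR replicate 3 the proteasome list changed direction (camera adjusted p = 0.63), and heat shock, chaperones, the NRF2 list, matrix, alternative activation and neuronal genes no longer passed (camera adjusted p 0.12 to 0.63). With the GC and length correction the proteasome and neuronal lists did not pass (camera adjusted p = 0.12 for both).

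The interaction term asks whether acrylamide acts differently with conditioned medium than without it. No single gene passed. EdgeR called 0 higher and 0 lower, with 347 of 12550 at an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0. In simulation this test found 4.48% of 2-fold differences. As lists, extracellular matrix genes responded less negatively with conditioned medium, by a median of 0.66, with 17 of 18 members positive and 4 higher over the list alone (camera adjusted p = 6.7e-09, and 0.011 with an estimated correlation). Without PBS-CM replicate 1 and PBS-CM+ACR replicate 3 that median was 0.379, and with all libraries fry gave adjusted p = 0.050 in one direction and 0.088 in either. MHC class I presentation (median -0.41, 0 of 14 called by edgeR, 1 lower over the list alone, camera adjusted p = 1.3e-05, and 0.0091 with an estimated correlation) and NF-kB targets (median -0.45, 0 of 12 over all genes and over the list alone, camera adjusted p = 0.00057, and 0.016 with an estimated correlation) responded less positively, and fry gave them adjusted p = 0.00034 and 0.0049 in one direction and 0.19 each in either. The NRF2 list (median -0.26, camera adjusted p = 0.00042) and heat shock response (median -0.31, camera adjusted p = 0.014) were lost with an estimated correlation, at adjusted p = 0.27 and 0.30, and heat shock also without those 2 libraries, at camera adjusted p = 0.072.

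**Figure D3:**
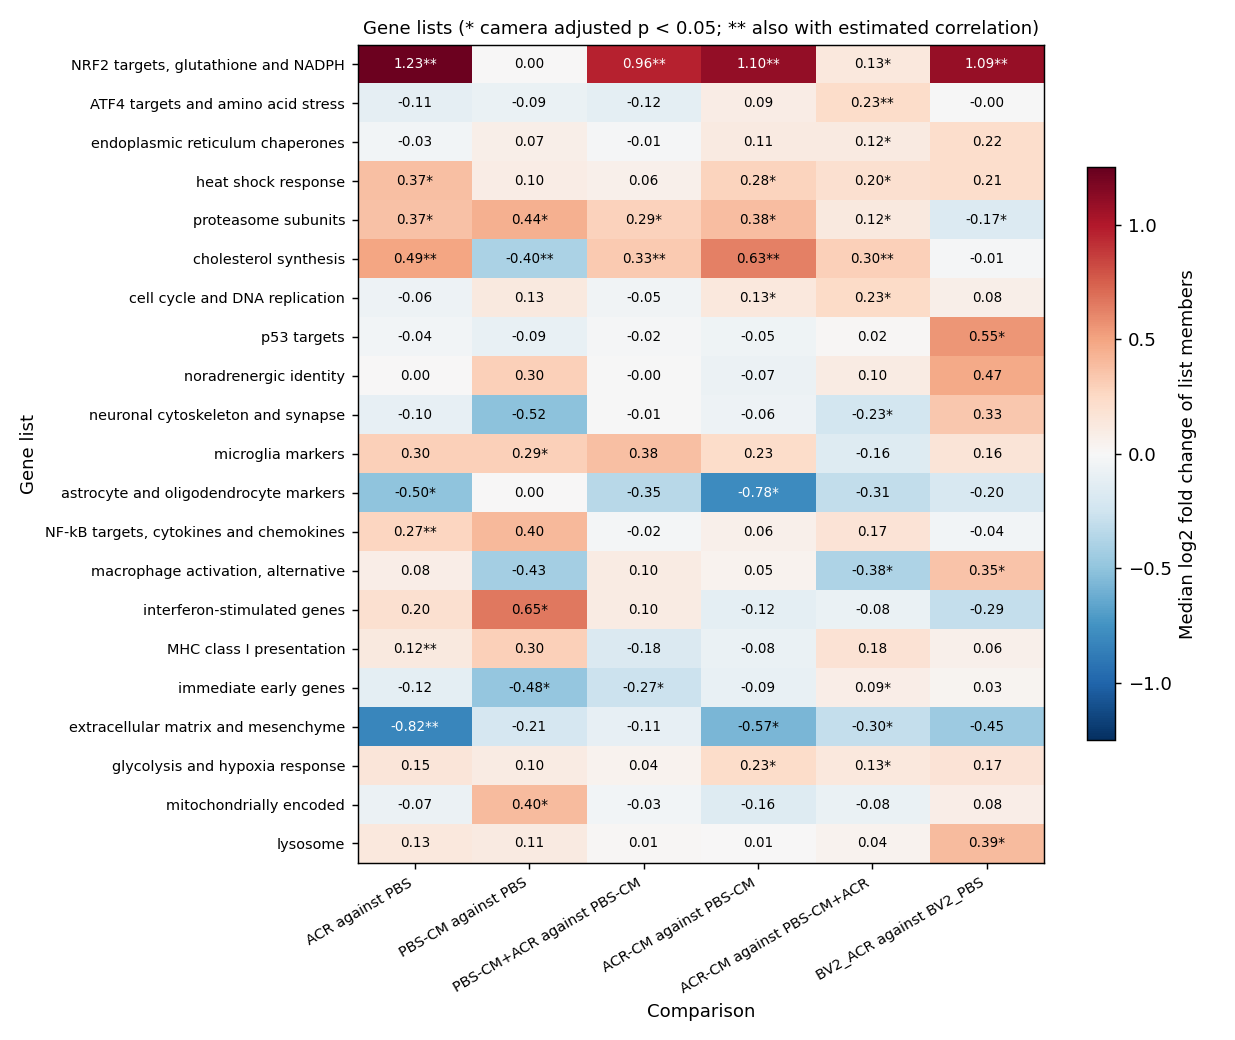
Median log2 fold change (colour and number) of 21 gene lists (rows) in the 6 pairwise comparisons (columns), with * for a camera adjusted p below 0.05 and ** where that also held with an estimated correlation. The NRF2 list had a median of 1.23 in ACR, 0.96 in PBS-CM+ACR, 1.10 in ACR-CM and 1.09 in BV2.

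Fold changes of the comparisons were then set side by side across genes, which are not independent replicates. ACR against PBS and PBS-CM+ACR against PBS-CM, which share no library, had Pearson r = 0.475 and Spearman rho = 0.43 over 12550 genes. They had 15 higher and 16 lower genes in common, where independent lists would share 0.102 and 0.179, and 143 of the 148 genes called in ACR had the same sign. The shared increases included Prdx6, Nqo1, Gclm, Srxn1 and Txnrd1, and the shared decreases Ccnd1, Tenm4, Slc1a3, Aqp1, Ptn and Neat1. ACR against PBS and ACR-CM against PBS-CM, a pairing chosen after the data had been seen, had r = 0.54 and rho = 0.498 with 29 higher and 24 lower genes in common (0.259 and 0.43 for independent lists). With genes of at least 20 CPM these r values were 0.686 and 0.716. PBS-CM+ACR and ACR-CM share their PBS-CM control. Their r was 0.636 and rho 0.593 with a covariance of 0.114, while simulated unchanged groups gave an r of 0.475 and a covariance of 0.05. They had 19 higher and 14 lower genes in common (0.0982 and 0.12 for independent lists), and part of that may come from the shared controls.

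In BV2 cells acrylamide again raised antioxidant genes. Gclm rose 4.97-fold, from 36.2 ± 1.09 to 180 ± 22.8 CPM (log2 2.31 ± 0.14, n = 3 per group, edgeR adjusted p = 2.2e-09), Blvrb from 48.9 ± 6.56 to 253 ± 43.3 CPM and Gstm1 from 73.3 ± 7.53 to 345 ± 25.0 CPM. Gdf15, a stress-induced cytokine, rose from 8.10 ± 0.40 to 46.2 ± 8.78 CPM and Rpph1, the RNA component of RNase P, from 20.1 ± 3.00 to 157 ± 35.0 CPM. Ribosomal protein transcripts were among the strongest decreases, such as Rps7, from 5120 ± 700 to 2090 ± 188 CPM. In all, 781 genes were higher and 1016 lower, with 3243 of 10890 at an unadjusted p under 0.05.

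Of 25 NRF2 list genes, 20 rose and 0 fell, 21 and 0 when adjusted over the list alone (median 1.09, camera adjusted p = 1.5e-16, and 0.024 with an estimated correlation). Txnrd1, a thioredoxin reductase, rose by 1.95 ± 0.15, Gsr, the glutathione reductase, by 1.71 ± 0.25, and Srxn1 by 1.45 ± 0.14. Outside the list Mgst1, a microsomal glutathione transferase, rose by 1.81 ± 0.12 and Cat, the catalase gene, by 1.60 ± 0.17. Nqo1 went from 0.16 CPM, close to no counts, to 10.9 CPM. Lysosome genes had 15 of 27 higher and 0 lower, 17 and 0 over the list alone (median 0.39, camera adjusted p = 2.4e-07, and 0.15 with an estimated correlation), with Psap at 1.28 ± 0.14, Sqstm1 at 1.16 ± 0.13, Ctsd at 0.88 ± 0.13 and Ctsb at 0.70 ± 0.13. Lipa, the lysosomal acid lipase, rose by 1.62 ± 0.13 and Mpeg1, a pore-forming macrophage protein, by 1.65 ± 0.15. Targets of p53 had 7 of 16 higher and 1 lower, 10 and 2 over the list alone (median 0.55, camera adjusted p = 7.8e-05, and 0.15 with an estimated correlation). Among them Trp53inp1, Ccng1, Phlda3 and Cdkn1a, which encodes the p21 inhibitor of cell cycle kinases, rose by 1.65 ± 0.36, 1.42 ± 0.15, 1.28 ± 0.18 and 0.92 ± 0.16.

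Alternative macrophage activation had 4 of 13 higher and 0 lower, over all genes and over the list alone (median 0.35, camera adjusted p = 0.016, and 0.20 with an estimated correlation), namely the mannose receptor Mrc1 at 1.31 ± 0.25, the lectin Clec10a at 1.07 ± 0.23, the scavenger receptor Cd36 at 0.95 ± 0.25 and Gas6 at 0.50 ± 0.13. Proteasome subunits had 5 of 31 lower and 1 higher, 7 and 1 over the list alone (median -0.17, camera adjusted p = 0.013, and 0.58 with an estimated correlation). After the correction for GC content and length the proteasome list no longer passed, at camera adjusted p = 0.36. NF-kB targets did not pass as a list (camera adjusted p = 0.20), but the chemokine genes Ccl7, Ccl4, Ccl3 and Ccl2 changed by -1.52 ± 0.27, -0.78 ± 0.16, -0.77 ± 0.13 and -0.63 ± 0.13. The acute-phase gene Saa3 and Tnfaip2, both inducible in inflammation, rose by 2.23 ± 0.24 and 1.52 ± 0.14. Of 19 microglia markers 1 was higher (Itgam at 1.06 ± 0.14) and 3 were lower (Tyrobp at -0.74 ± 0.17, Fcer1g at -0.49 ± 0.13 and C1qb at -0.49 ± 0.16), over all genes and over the list alone (camera adjusted p = 0.86). Glycolysis and hypoxia (6 higher and 2 lower of 23), cholesterol synthesis (1 and 1 of 21) and interferon-stimulated genes (0 and 2 of 10) gave camera adjusted p = 0.38, 0.92 and 0.17, and the other lists did not pass either.

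The ranked decreases were -1.53 ± 0.17 for Rpl22l1, -1.44 ± 0.22 for the small nucleolar RNA Snord15b, -1.38 ± 0.17 for Pet100, -1.28 ± 0.17 for Pin4, -1.24 ± 0.17 for Rpl37, -1.20 ± 0.21 for Ubl4a, -1.19 ± 0.19 for Rpl34, -1.19 ± 0.17 for Rpl27, -1.19 ± 0.19 for Rps15a, -1.18 ± 0.17 for Cyp2e1 and -1.18 ± 0.14 for Clec5a. Ribosomal protein genes took 19.0 to 21.4% of the counts in BV2_PBS and 13.1 to 15.9% in BV2_ACR. Of the 79 that could be tested, a set defined after this was seen, 70 were lower and 0 higher by edgeR. The number of called genes in BV2 was 913 and 1092 without BV2_PBS replicates 1 and 2 and 1044 without BV2_ACR replicate 2. Tested against a 1.5-fold change, 115 genes passed.

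**Figure D4:**
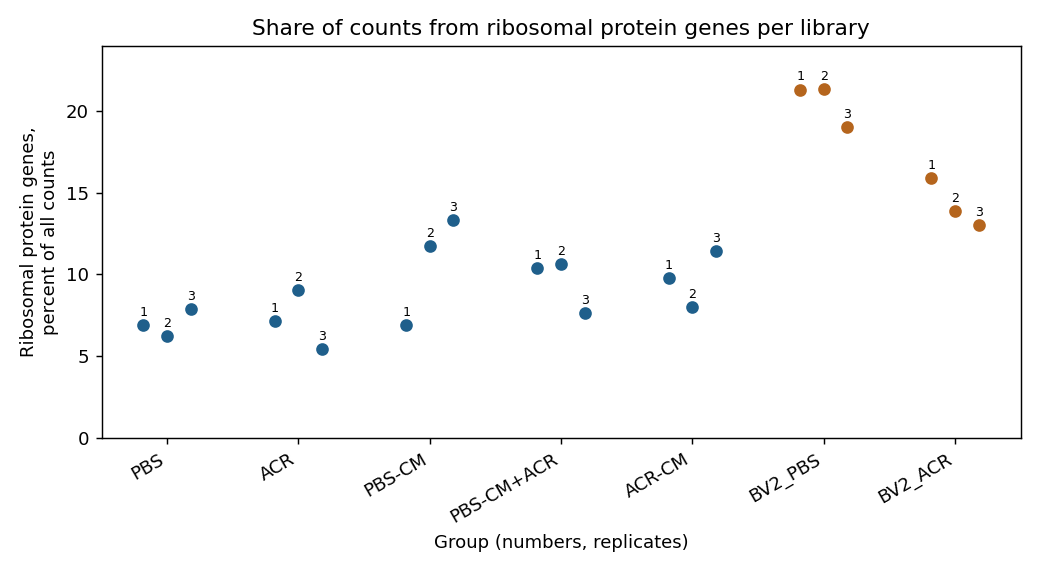
Share of all counts in ribosomal protein genes (y axis, percent) in each of the 21 libraries (points numbered by replicate), by group (x axis), with 1C11NE in blue and BV2 in orange. BV2_ACR libraries lay between 13.1 and 15.9%, below the BV2_PBS libraries at 19.0 to 21.4%, and PBS-CM replicate 1 lay at 6.93% against 11.8 and 13.4% in the other two PBS-CM libraries.

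The last comparison subtracts the acrylamide effect in 1C11NE from that in BV2. Ccnd1 and Plpp3, a lipid phosphatase, were more positive in BV2 by 2.04 ± 0.26 and 1.87 ± 0.24 on the log2 scale, and Prdx6 and Gstp1 less positive, by -2.47 ± 0.24 and -2.12 ± 0.29 (n = 3 per group, edgeR adjusted p = 0.00044, 0.00045, 5.4e-06 and 0.00059). Ccnd1 was called lower in each line, at a log2 change of -2.55 in 1C11NE and -0.51 in BV2. In all, 46 genes were more positive in BV2 and 31 less, with 2012 of 13569 at an unadjusted p under 0.05. Corrected for GC content and length, 130 and 200 were. Targets of p53 were more positive in BV2, with 5 of 18 called and 8 over the list alone (median 0.59, camera adjusted p = 4.2e-06, and 0.0020 with an estimated correlation). They included Gdf15 at 1.75 ± 0.25, Trp53inp1 at 1.72 ± 0.40, Cdkn1a at 1.64 ± 0.29 and Phlda3 at 1.46 ± 0.26. Lysosome genes were also more positive, with 1 of 27 called, Psap at 1.21 ± 0.28, and 3 over the list alone (median 0.41, camera adjusted p = 0.00011, and 0.019 with an estimated correlation). Extracellular matrix genes (0 of 18 by edgeR, 2 over the list alone, median 0.99) and astrocyte and oligodendrocyte markers (0 of 6 by edgeR, median 0.48) passed camera at adjusted p = 4.2e-06 and 0.036, and gave adjusted p = 0.029 and 0.22 with an estimated correlation. Only 3 members of each could be tested in BV2, so no difference of response between the lines is read from them. Over those 3, in a test chosen after the data had been seen, camera gave adjusted p = 0.18 and 0.63.

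Less positive in BV2 were cholesterol synthesis (1 of 22, the farnesyl diphosphate synthase gene Fdps, and 8 over the list alone, median -0.52, camera adjusted p = 0.00014, and 0.048 with an estimated correlation) and NF-kB targets (2 of 19, Ccl7 at -2.52 ± 0.37 and Ccl2 at -1.59 ± 0.33, over all genes and over the list alone, median -0.33, camera adjusted p = 0.0037, and 0.024 with an estimated correlation). Ccl2 was not called without any 1 library but ACR replicate 3 or BV2_PBS replicate 3 (edgeR adjusted p 0.050 to 0.082). Interferon-stimulated genes (1 of 20, Xaf1 at -1.11 ± 0.24, median -0.61) and proteasome subunits (0 of 31 by edgeR, 10 over the list alone, median -0.49) passed camera at adjusted p = 0.0017 and 5.3e-08, and gave adjusted p = 0.12 and 0.25 with an estimated correlation. With only genes tested in each line, an estimated correlation gave camera adjusted p = 0.085 for cholesterol synthesis, NF-kB targets (10 members, median -0.079) and interferon-stimulated genes (9 members). The NRF2 list did not differ as a list, with 1 member more positive and 2 less of 26, 5 and 3 over the list alone (median 0.10, camera adjusted p = 0.74). Across 9919 genes tested in both lines the log2 changes of ACR against PBS and of BV2_ACR against BV2_PBS had r = 0.093 and rho = 0.0393. They had 26 higher genes in common, where independent lists would share 3.14, and 3 lower, where 3.15 would be shared. The shared increases included Prdx6, Gclm, Srxn1, Blvrb and Gdf15, and the shared decreases included Ccnd1.

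The count of 77 between the lines was 30, 43 and 50 without PBS replicates 1, 2 and 3, 46 and 35 without ACR replicates 1 and 2, 25, 37 and 47 without BV2_PBS replicates 1, 2 and 3, and 48, 34 and 44 without BV2_ACR replicates 1, 2 and 3.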

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

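Chosen only after the result was seen were the tests of wrong labels and of RNA carried over from BV2 cells, the test of library scaling on ribosomal protein transcripts, the list tests on genes tested in each line, and the tests of the matrix list with the GC and length correction and without 2 libraries.

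Differences of the acrylamide response within 1C11NE stood out by the interaction term over whole gene lists. With conditioned medium minus without it, the median log2 difference was 0.66 for the 18 extracellular matrix genes, -0.45 for the 12 NF-kB targets, -0.41 for the 14 MHC class I genes, -0.31 for the 16 heat shock genes and -0.26 for the 26 NRF2 list genes, the last 2 lost with an estimated correlation (camera adjusted p = 0.30 and 0.27). Over single genes the same term called 0 of 12550 genes with edgeR, with 347 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom. All 100 of 100 drawn splits of these libraries reach a count of 0, as any split must, so they say nothing about chance here. The highest other split called 1081, which points to a structure of the samples.

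Between the lines, 77 genes stood out by the interaction term. In 3 of 100 drawn splits, the real one included, as many genes were called, a share under the 0.05 set beforehand. The median of the other splits was 0 genes. Splits that mix treated and untreated libraries do not picture lines that respond alike, so they do not exclude chance. The highest other split gave 333, and it exchanges ACR and PBS in 1C11NE, so that it adds the effects of the 2 lines. Among genes more positive in BV2 the log2 differences were 2.85 for the transcription factor Nfatc2, 2.04 for Ccnd1 and 1.87 for Plpp3. Ccnd1 fell in each line, and by less in BV2. For Nqo1 and Cd55, a complement regulator, the differences were 4.06 and 3.31, fitted values with no bound, since BV2_PBS held almost no counts of either. Cd55 stood at 0.29 ± 0.28 CPM in BV2_PBS and 1.57 ± 0.31 in BV2_ACR, too low to be tested in BV2 alone. Of the 77 genes, 3 (Arvcf, Cd55 and Pycr1) were not tested in each line. Less positive in BV2 were Prdx6 at -2.47, Gstp1 at -2.12, the hyaluronan receptor Layn at -1.96, the small nucleolar RNA Snora73b at -1.61, the mitophagy gene Bnip3 at -1.60 and the chemokine Ccl2 at -1.59. Calls ended for Cd55 without BV2_PBS replicate 1 (edgeR adjusted p = 0.063), for Bnip3 without PBS replicate 1 (0.061), for Snora73b without any library but PBS replicate 3, BV2_PBS replicate 3 and BV2_ACR replicate 1 (0.059 to 0.11), and for Ccl2 without any but ACR replicate 3 and BV2_PBS replicate 3 (0.050 to 0.082). As whole lists, p53 targets (median log2 difference 0.59) and lysosome genes (0.41) passed camera, also with an estimated correlation and with only genes tested in each line. NF-kB targets (-0.33) and cholesterol synthesis (-0.52) passed camera with both correlations, but over the 10 and 21 members tested in each line an estimated correlation gave camera adjusted p = 0.085 for both. Proteasome subunits (-0.49) and interferon-stimulated genes (-0.61) were lost with an estimated correlation (camera adjusted p = 0.25 and 0.12). Extracellular matrix genes (0.99) and astrocyte and oligodendrocyte markers (0.48, and lost with an estimated correlation at camera adjusted p = 0.22) had 3 of 18 and 3 of 6 members tested in BV2. Over those members they no longer passed (camera adjusted p = 0.18 and 0.63), so no difference of response between the lines is read from them.

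The first pattern weighed is that PBS-CM replicate 1 and PBS-CM+ACR replicate 3 stand apart from their groups, at 0.649 and 0.688 log2 units where the highest of the other 13 libraries of 1C11NE is at 0.531. Wrong labels, meaning libraries without conditioned medium, are argued against for PBS-CM replicate 1. Over 50 medium-responsive genes it lies at 0.635 on a scale from 0 in PBS to 1 in the other PBS-CM libraries, with PBS libraries between -0.10 and 0.093. Over 50 called and expressed genes it lies at 0.481, with PBS libraries between -0.17 and 0.17. A stricter bound set earlier was missed, and the one used here was set after the positions were seen. PBS-CM+ACR replicate 3 lies at 0.88 and 0.525, on a scale that ends at 1 in the other PBS-CM+ACR libraries. Without conditioned medium it would be an ACR library, and ACR libraries were not placed on the scale, so its label stays open. BV2 RNA carried into the other conditioned-medium libraries is argued against too, since their ribosomal protein share of 10.8% against 7.01% in PBS would need 27.7% of BV2 RNA, and 5 abundant BV2 transcripts exceed their PBS level by at most 0.876% of their BV2 level. GC content and transcript length may account for part, as correction lowered the ratio of their distance to the median of the others from 1.59 to 1.40, and that part cannot be told apart from other causes because the 2 still lay above all others (0.514 and 0.585 against 0.486). A weaker dose of conditioned medium, which such middle positions allow, stays open and untested.

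The second pattern is the decrease of ribosomal protein transcripts in BV2_ACR, with a median log2 change of -0.82 over 79 genes. Length and GC content of the longest annotated transcript are argued against as the whole cause, because 0 of 10000 gene sets matched on both had a median as low (matched median -0.19, 95% between -0.29 and -0.073), although the correction lowered the size to -0.60 with 63 genes still called lower. The expressed transcript can be shorter than the longest annotated one, and an effect of its length was not tested. Scaling is argued against as the whole cause, as it moved the median of all genes by at most 0.265, to 0.28 with total counts, under which ribosomal protein genes still stood at -0.57. A stricter bound on that move was missed, and the one used here was set after the move was seen. Reads assigned to pseudogenes instead are argued against, since 12 pseudogenes changed by -4.48% of the loss, that is, they fell as well. That acrylamide lowers these transcripts in BV2 remains a hypothesis, found and tested in the same libraries.

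The third pattern is the matrix list, which fell with acrylamide without conditioned medium (median -0.82) and had a median of -0.11 with it, but fell by a median of -0.57 in ACR-CM against PBS-CM (camera adjusted p = 0.00031, and 0.11 with an estimated correlation). GC content and length, or the 2 libraries that stand apart, are argued against as the whole cause, since the median difference of 0.66 was still 0.566 with the correction and 0.379 without those libraries. A floor reached because conditioned medium had already lowered the genes is argued against as the whole cause too, as the 7 members not lower in PBS-CM had a median difference of 0.484, all 7 positive, between 0.081 and 1.15. A partial floor stays open, with 0.98 over the lower members, though the same PBS and PBS-CM libraries sort the members and enter the difference. A modifying effect of the medium remains a hypothesis that the fall in ACR-CM does not support, and fry gave adjusted p = 0.050 in one direction and 0.088 in either.

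For the pairwise comparisons 10 splits of 6 libraries exist, too few for a share under 0.05. In 1 of 10 splits, the real one, as many genes were called for ACR against PBS (148, with 0 in the highest other split), PBS-CM against PBS (571 and 0), ACR-CM against PBS-CM (116 and 0), ACR-CM against PBS-CM+ACR (2 and 0) and BV2 (1797 and 0). For PBS-CM+ACR against PBS-CM, 2 of 10 did, with 47 in the real split and 923 in the other. That split sets PBS-CM replicate 3 and PBS-CM+ACR replicates 1 and 2 against PBS-CM replicates 1 and 2 and PBS-CM+ACR replicate 3, and points to a structure of these samples.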

How the results depend on the processing

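Tests with the GC and length correction, alone or with the block, without 2 libraries, and with only genes tested in each line were chosen only after the data had been seen. In this order, ACR against PBS, PBS-CM against PBS, PBS-CM+ACR against PBS-CM, ACR-CM against PBS-CM, ACR-CM against PBS-CM+ACR, the conditioned medium interaction and the interaction between lines called 148, 571, 47, 116, 2, 0 and 77 genes, and BV2 called 1797. DESeq2 called 306, 1222, 124, 278, 15, 3 and 565. The GC and length correction gave 360, 894, 150, 342, 11, 2 and 330, holding 145 of the 148, 450 of the 571, 47 of the 47, 113 of the 116 and 72 of the 77. No filter gave 351, 1372, 136, 459, 13, 2 and 234 among more genes tested. A fold threshold of 1.5, a stricter question by construction, gave 40, 49, 5, 17, 1, 0 and 12, and 115 in BV2. Without PBS-CM replicate 1 and PBS-CM+ACR replicate 3, counts moved to 554, 4479, 4 and 2 for ACR against PBS, PBS-CM against PBS, ACR-CM against PBS-CM+ACR and the conditioned medium interaction, and were 62 for PBS-CM+ACR against PBS-CM and 174 for ACR-CM against PBS-CM. Fits of only the 6 compared libraries gave 362, 210, 0, 15 and 0 for the 5 comparisons in 1C11NE, with 536 and 450 genes at an unadjusted p under 0.05 where edgeR called 0. A filter at 20 CPM gave 1 for ACR-CM against PBS-CM+ACR and 129 between lines. The r of ACR against PBS with PBS-CM+ACR and with ACR-CM moved to 0.686 and 0.716 among genes of at least 20 CPM. DESeq2's size factors in edgeR and limma-voom moved no count of called genes by over 1.5 times. The cause was not tested for any of these unless the setting itself names it.

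In 1C11NE no pairing of libraries by replicate number was seen, while in BV2 a weak pairing stays open. Deviations of libraries with the same number had correlations from -0.547 to 0.439 (median -0.029, 30 pairs) in 1C11NE and from 0.029 to 0.117 in BV2, and 9 of 21 libraries correlated best with their own number. Different numbers in BV2 gave -0.082 to 0.041. With the replicate number as a block 309, 21, 56 and 43 genes were called for PBS-CM against PBS, PBS-CM+ACR against PBS-CM, ACR-CM against PBS-CM and between lines, and the other comparisons moved by less than 1.5 times. Among these, BV2 rose from 1797 to 2355. The correction together with the block gave 265 for ACR against PBS, 206 for ACR-CM against PBS-CM, 7 for ACR-CM against PBS-CM+ACR, 2 for the conditioned medium interaction and 237 between lines.

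Leaving out each library in turn gave 71 to 109 genes for ACR against PBS, 106 to 3233 for PBS-CM against PBS, 11 to 73 for PBS-CM+ACR against PBS-CM, 35 to 93 for ACR-CM against PBS-CM, 2 to 3 for ACR-CM against PBS-CM+ACR, 0 to 2 for the conditioned medium interaction, 25 to 100 between lines and 913 to 1883 in BV2. The lowest values arose without PBS replicate 1 (71), PBS-CM replicate 2 (106 and 11), ACR-CM replicate 1 (35) and BV2_PBS replicate 1 (25 and 913), and the highest of PBS-CM against PBS and PBS-CM+ACR against PBS-CM without PBS-CM replicate 1 (3233) and PBS-CM+ACR replicate 3 (73). The 2 of the conditioned medium interaction arose without PBS-CM replicate 1. The r between PBS-CM+ACR and ACR-CM was 0.661 to 0.722 when a PBS-CM library was left out. Unchanged groups were not simulated with fewer controls, so these r values have no matching value without an effect.

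All 133 genes named by rank kept their direction and call with DESeq2's size factors and with the correction. With the block 21 lost the call, Nrp2 and Gfra1 in ACR against PBS (edgeR adjusted p = 0.11 and 0.068), Ftl1, Gstp1, Taldo1, Gstp2, Cd248, Hist1h2ap, Hist1h2ag, Tenm4, Aqp1 and Rin1 in PBS-CM+ACR against PBS-CM, Dennd4b, Gfra1, Npr2, Oaf, Klhdc8a, Tenm4 and Aqp1 in ACR-CM against PBS-CM, and Snora73b and Ccl2 between lines. When 1 library was left out the call ended for Cd248, Nrp2, Adamts1 and Gfra1 in ACR against PBS (highest edgeR adjusted p 0.11, 0.21, 0.12 and 0.17), and for Bst2, Fgl2, Apcdd1, Fam43a and Lrig1 in PBS-CM against PBS. In PBS-CM+ACR against PBS-CM it ended for those 10 genes and Esd, Pgd, Idi1, Ptn, Ren1, Slc1a3 and Etnk2, in ACR-CM against PBS-CM for those 7 and Gsta4, Cc2d2a and Smim1, and between lines for Snora73b, Ccl2, Cd55 and Bnip3. Of 56 list results past camera's threshold, 21 held and 35 were lost with an estimated correlation, and with fry 38 held in one direction and 37 in either. The block ended none. With the correction 51 held, 4 were lost (microglia markers in PBS-CM against PBS, proteasome and neuronal genes in ACR-CM against PBS-CM+ACR, and proteasome in BV2) and the mitochondrially encoded list in PBS-CM against PBS reversed (camera adjusted p = 0.00053). Without the 2 libraries 34 held, 8 were lost (microglia markers in PBS-CM against PBS, heat shock in the conditioned medium interaction, and the NRF2 list, chaperones, heat shock, neuronal genes, alternative activation and matrix in ACR-CM against PBS-CM+ACR) and the proteasome list in ACR-CM against PBS-CM+ACR reversed (camera adjusted p = 0.63). With only genes tested in each line, 6 of 8 lists between lines held and extracellular matrix and astrocyte and oligodendrocyte markers, with 3 members each, were lost (camera adjusted p = 0.18 and 0.63). The cause was not tested. Of simulated 1.5-fold changes 1.49% and 0.0% were called in the interactions and 1.49 to 22.4% in the pairwise comparisons, and of 2-fold changes 4.48% and 7.46% against 37.3 to 68.7%.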

Other observations

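The test of how far ACR-CM resembles PBS-CM+ACR was chosen only after the result was seen, and the list of steroid-producing cell markers was written after Star and Akr1b7 had been seen but before its own genes were looked at.

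The libraries labelled 1C11NE held few transcripts of a noradrenergic neuron. Of 18 noradrenergic identity genes 12 were in the table and 3 reached 20 CPM in PBS (n = 3), and of 29 neuronal cytoskeleton and synapse genes 27 were in the table and 5 did. Th and Dbh, members of the noradrenergic list, were not in the table. The 12 that were summed to 193 ± 7.25 CPM in PBS, below the 588 ± 4.15 CPM in BV2_PBS. Neural adhesion molecule Ncam1 stood at 787 ± 93.1 CPM and the microtubule protein gene Map1b at 117 ± 7.24, but the neuronal tubulin Tubb3 at 2.66 ± 0.47, the noradrenaline transporter Slc6a2 at 1.961 ± 0.75 and the neuroblast factor Hand2 at 0.69 ± 0.54. Gch1, which makes the cofactor of catecholamine synthesis, stood at 31.4 ± 3.23 CPM. BV2_PBS in turn held the neurofilament gene Nefh at 35.0 ± 4.63 CPM, Ina at 16.1 ± 1.64 and Uchl1 at 77.0 ± 2.3, against 0, 0.41 ± 0.47 and 0.40 ± 0.098 in PBS, and the stem cell genes Dnmt3l at 14.0 ± 1.92 and Nanog at 10.5 ± 2.91. Nanog has pseudogene copies, so its value is uncertain.

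Genes of hormone-producing tissue were seen in 1C11NE instead. Ren1, the renin gene, stood at 60.9 ± 8.16 CPM in PBS, Foxl2, an ovarian and pituitary transcription factor, at 69.0 ± 4.01, Insl3, a gonadal peptide, at 49.0 ± 15.4, and the inhibin subunit Inha at 22.7 ± 5.04. Star, which carries cholesterol into mitochondria, stood at 7.84 ± 2.22 CPM in PBS, 19.0 ± 0.70 in ACR and 24.6 ± 5.38 in PBS-CM. In BV2_PBS these were 0 for Ren1 and Inha, 8.07 ± 2.37 for Foxl2, 1.87 ± 0.69 for Insl3 and 0.63 ± 0.40 for Star. A candidate source is a cell with the transcripts of a steroid-producing cell. Of its 16 markers, none held by another list, 10 were in the table and 2 reached 20 CPM in PBS with a level over 10 times lower in BV2_PBS, where at least 4 were asked for and at most 1 would have spoken against it. The steroid-forming enzyme genes Cyp11a1 and Cyp17a1 stood at 0.048 ± 0.083 and 0.25 ± 0.23 CPM, so the test leaves the question open.

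A second hypothesis concerns the medium from acrylamide-treated microglia. Its effect might come from acrylamide still present in it, since the labels do not state a removal. Over the 148 genes called in ACR against PBS, the median change in the direction of ACR was 0.845 in ACR-CM and 0.788 in PBS-CM+ACR, a ratio of 1.07, and 141 and 143 of the genes kept their sign. Both medians use the same PBS-CM libraries, and an interval from resampled genes (0.942 to 1.18) leaves out the spread between libraries. Compared directly, the median difference over these genes was 0.0865, but ACR-CM was higher in cholesterol synthesis (median 0.30, camera adjusted p = 7.5e-06, and 0.019 with an estimated correlation) and ATF4 targets (camera adjusted p = 0.00070, and 0.019). The summed level of ATF4 targets in ACR-CM, 6380 ± 200 CPM, did not exceed the 6415 ± 49.9 CPM in PBS-CM. Carried-over acrylamide and products of stressed microglia thus cannot be told apart, because the labels do not state whether acrylamide was removed from that medium.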
